A study of Homo sapiens with 18 samples.

How the data were processed

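RNA sequencing of 22RV1 cells was analysed in 6 libraries, 3 from cells given the solvent DMSO (vehicle) and 3 from cells given 10 µM UT-143 for 20 to 24 hours. 22RV1 is an established human prostate cancer line. UT-143 is the compound under test. The labels number the samples in each group but do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical. The series lists 18 samples. The 12 ATAC-seq (open chromatin) samples of 22RV1 and LNCaP were not analysed here.

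The deposited table gives 1 value per library for each of 35246 Ensembl transcript identifiers. Its name calls the values CPM (read counts scaled to a common library total), and each library column holds whole numbers, so the deposited values were treated as a normalized score, CPM rounded by the authors, and not as raw counts. The 3 vehicle values of a row had a median variance-to-mean ratio of 0.071, far below the value of 1 that counting error gives for raw counts. Rounding leaves an uncertainty of up to 0.5 units, which is 3.8% of the median value of 13 in vehicle replicate 1 and a large part of a value of 1. The depth in reads is unknown, so no counting intervals were made, and no reads could be recovered from whole numbers. No row sums to less than 30 over the 6 libraries, so transcripts with a mean under 5 CPM are not listed. The submitters' processing notes name FastQC, STAR 2.7.10a, HOMER and build hg38. How reads were counted per transcript, how reads shared by several transcripts were treated and whether strand was used are not given in the sources used here. All 6 values of 12590 rows (35.7%) were equal to those of another row. The deposited table also holds the authors' group means, a ratio of means, a signed fold and an unadjusted p-value. The deposited p-value equalled a 2-sided unequal-variance test of the linear values within 1e-06 in 35054 rows, and the other 192 rows hold a spreadsheet error.

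Groups came from the sample titles, and columns were matched to samples by the identifier in each sample's description. No column of per-sample values was left unmatched. Of the 35246 transcript identifiers, 0 were found in the gene ID table and 0 in the RefSeq table used for names, and the deposited table pairs none with a gene. Gene symbols, chromosomes and positions are therefore not given. For the same reason the 28 gene lists fixed in advance (cell cycle, stress responses, markers of other cell types and others) and their set tests were not run.

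Values were transformed as log2(CPM + 1), and every fold change below is on that scale, which understates the change of low rows. The groups were compared with limma 3.58.1 in R 4.3.3 (linear model with group as the only term, empirical Bayes moderation with a mean-variance trend, Benjamini-Hochberg adjustment, threshold 0.05). A filter of CPM 1 or more in at least 3 libraries removed 0 rows. Transcripts were named by a rule: the largest rises and falls among rows past the threshold whose UT-143 values all lay on one side of the vehicle values and whose mean was at least 5 CPM. The rule asked for 10 in each direction, and only the first 2 in each are printed, since they cannot be named as genes. The tests, the rule and most alternatives were fixed before the data were examined. The alternatives were other pseudocounts, filters, scalings, moderation settings and thresholds, the replicate number as a block, and each library left out in turn. The fit without UT-143 replicate 3 was one of these, and its own alternatives and a fit with limma array weights were added after seeing the data. Figures were drawn with Matplotlib 3.10.9.

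Whether the numbers shared by the groups pair the samples could not be settled. The deviations from the group means of same-numbered libraries correlated at -0.41, 0.52 and 0.04 across transcripts. UT-143 replicate 3 dominates the deviations in its group, with a standard deviation of 0.41 against 0.23 and 0.21 for UT-143 replicates 1 and 2. The check therefore cannot exclude pairing.

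The fit was tested on simulated rounded values for 35246 rows. The 200 changed rows were drawn from those with a mean of at least 10 CPM, so recovery below that was not tested. The spread of each row came from the vehicle libraries, drawn toward the mean over rows, and was used for all libraries. Only UT-143 replicate 3 had added spread, taken from its difference to the mean of UT-143 replicates 1 and 2. With 6 libraries the fit recovered 28 of 100 rows changed by 1 on the log2 scale and 83 of 100 changed by 2, with 0 false calls. Without UT-143 replicate 3 it recovered 62 of 100 and 97 of 100, and it also called 139 of 35046 unchanged rows (0.397%). False calls were thus 139 of its 298 calls, a larger share than the nominal 0.05. Of those false calls, 138 had a mean under 10 CPM. Robust moderation was tried in the simulation after these false calls were seen. Without UT-143 replicate 3 it recovered all 100 at each size with 15 false calls, and with 6 libraries it recovered 30 of 100 and 85 of 100 with 0 false calls. Recovery at a given adjusted p depends on the share of changed rows. Here that was 200 of 35246, while the real fit without UT-143 replicate 3 called 23.3%. The recovered shares are therefore not the power of the real fits.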

Results

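The effect of UT-143 on the transcriptome of 22RV1 prostate cancer cells was measured by RNA sequencing of 3 vehicle and 3 UT-143 libraries, with UT-143 given at 10 µM for 20 to 24 hours. The comparison asks which transcripts differ after treatment with the compound. Values were rounded CPM for 35246 Ensembl transcripts. The listed values summed to between 889253 and 892558 CPM in the vehicle libraries, to 896070 and 900414 CPM in UT-143 replicates 1 and 2, and to 923170 CPM in UT-143 replicate 3. The 10 most abundant rows held between 6.60% and 8.40% of the listed total in the vehicle libraries, 8.18% and 8.93% in UT-143 replicates 1 and 2, and 5.69% in UT-143 replicate 3. The rows carry transcript identifiers without gene names, so results are given for transcripts as a whole and by abundance.

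UT-143 replicates 1 and 2 resembled each other and differed from vehicle, and UT-143 replicate 3 differed from all 5 other libraries. Across transcripts, log2(CPM + 1) correlated at 0.985 to 0.992 between vehicle libraries and at 0.993 between UT-143 replicates 1 and 2. Between vehicle libraries and UT-143 replicates 1 and 2 the correlation was 0.953 to 0.966. UT-143 replicate 3 correlated at 0.888 and 0.895 with the other UT-143 libraries and at 0.816 to 0.852 with the vehicle libraries. These are correlations across transcripts, which are not independent replicates. UT-143 replicate 3 listed 6674 transcripts at 5 CPM or less, against 2049 to 2868 in the other 5 libraries, and 31 transcripts at 0, against 0 in each of the others.

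**Figure D1:**
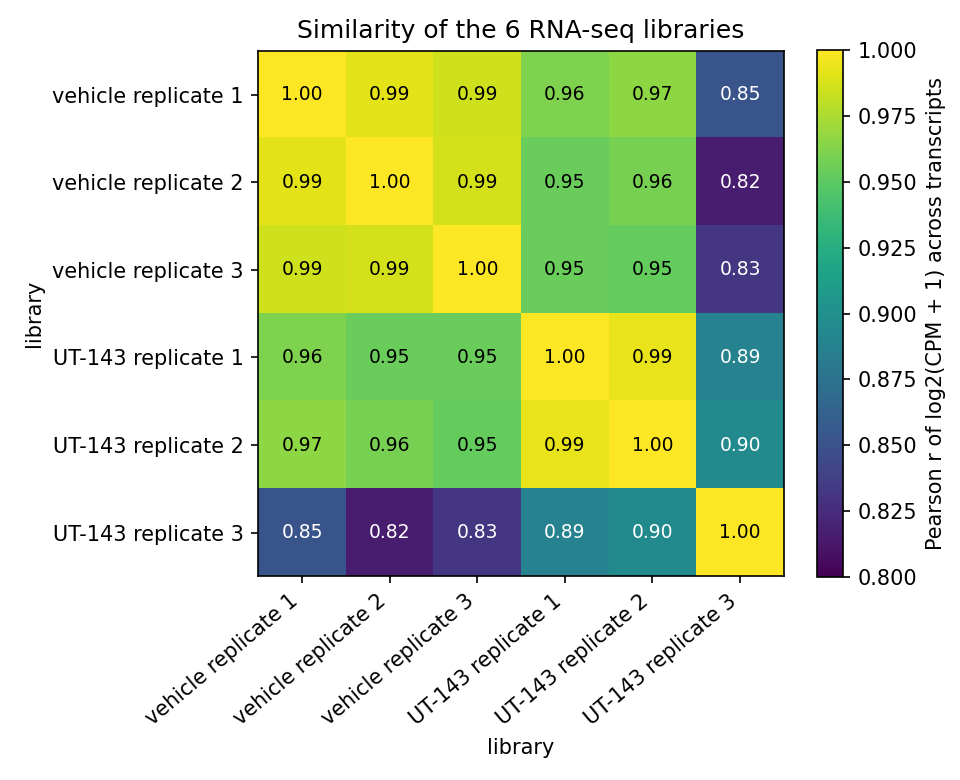
Pearson correlation of log2(CPM + 1) across transcripts for each pair of the 6 libraries, with the library on both axes and the correlation as colour and number. The 5 libraries other than UT-143 replicate 3 correlate at 0.95 or more with each other, and UT-143 replicate 3 reaches at most 0.90 with any of them.

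After UT-143, 456 transcripts were higher and 732 were lower than in vehicle-treated cells, 3.37% of the 35246 tested (limma, adjusted p under 0.05, n = 3 per group). The count of higher transcripts depended on the scaling between libraries: trimmed mean scaling gave 734 higher and 838 lower, median-of-ratios scaling 696 higher and 879 lower, and quantile normalization 1409 higher and 1966 lower. With the values as deposited, the median change was 0.77 on the log2 scale among the higher transcripts and -0.74 among the lower ones. Of the changed transcripts, 102 were higher by at least 1 on the log2 scale and 146 were lower by at least 1. All 1188 had their 3 UT-143 values entirely above or entirely below their 3 vehicle values. Rows whose groups overlap can hardly pass this threshold, so that is no separate support for the calls. Over all tested transcripts, 4617 had all UT-143 values above all vehicle values and 7849 had all below. Together these make 35.4% of transcripts, where chance gives 10% on average. Transcripts are not independent, so the share without an effect can lie far from that average. Its spread was not computed.

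The number of changed transcripts depended on single libraries. Without UT-143 replicate 3, 3048 transcripts were higher and 5158 were lower, 23.3% of those tested, and the 1188 transcripts called with 6 libraries were among them with the same direction. The groups of those 1188 did not overlap, so their direction could not differ between the fits. The changes of all transcripts called without UT-143 replicate 3 were smaller, with medians of 0.40 for the higher and -0.43 for the lower ones. In simulated data with 200 changed transcripts, 139 of the 298 calls of the 5-library fit were false, nearly all under 10 CPM. They came from 35046 unchanged transcripts, and their share of the calls was above the nominal 0.05. How many of the calls in the real data are false cannot be read from this. At a change of at least 1 on the log2 scale the fits with and without UT-143 replicate 3 gave similar counts, with 97 higher and 149 lower when it was left out. Similar counts do not show that the same transcripts passed this cutoff, and their overlap was not counted. Trimmed mean scaling moved the split of the 5-library calls to 5558 higher and 5923 lower. Leaving out any 1 of the other 5 libraries (each vehicle replicate, UT-143 replicate 1 or UT-143 replicate 2) gave 0 transcripts at an adjusted p under 0.05 in limma, with 5080 to 9271 transcripts at an unadjusted p under 0.05.

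**Figure D2:**
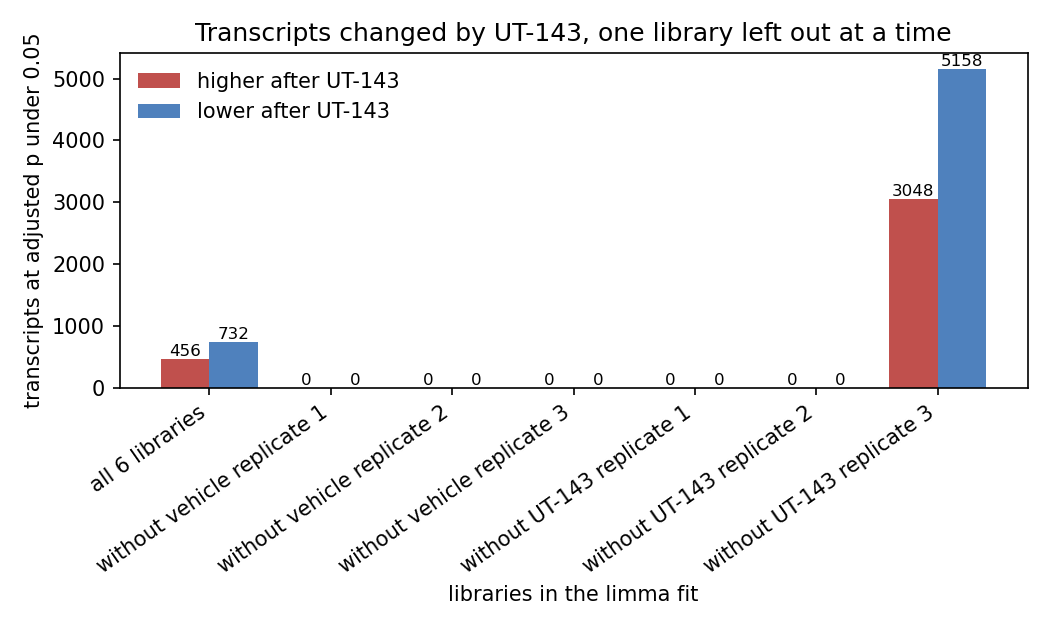
Number of transcripts higher (red) and lower (blue) after UT-143 at an adjusted p under 0.05 in limma, for all 6 libraries and with each library left out. The count is 456 higher and 732 lower with all 6 libraries, 3048 and 5158 without UT-143 replicate 3, and 0 without any 1 of the others.

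Changed transcripts were found at all levels of abundance. Of the 3144 transcripts with a mean of 50 CPM or more, 78 were higher and 59 were lower with 6 libraries. Among the 13395 transcripts with a mean under 10 CPM, 118 were higher and 205 were lower. In the levels between, 124 were higher and 242 lower at 10 to 20 CPM, and 136 higher and 226 lower at 20 to 50 CPM. Without UT-143 replicate 3, 354 transcripts were higher and 428 lower at 50 CPM or more, and 1000 were higher and 1827 lower under 10 CPM. In the simulation, 138 of the 139 false calls of this 5-library fit had a mean under 10 CPM. Whether the direction of change differs between levels was not tested.

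The largest rise was that of ENST00000612821.4, from 1.33 ± 0.58 CPM in vehicle (SD, n = 3) to 17.3 ± 6.5 CPM after UT-143 (SD, n = 3). Its change on the log2 scale was 2.94 with a standard error of 0.31 (limma, adjusted p = 0.027). ENST00000617691.4 rose from 1.33 ± 0.58 to 16.7 ± 6.5 CPM (SD, n = 3 each). The authors' deposited table gives ratios of means of 13 and 12.5 for this pair. The vehicle values were 1 or 2 CPM, so rounding limits the precision of these ratios. The change on the log2 scale also depends on the pseudocount. For ENST00000612821.4 it was 3.46 with a pseudocount of 0.25 and 1.96 with 4. The largest fall was that of ENST00000681704.1, from 32.3 ± 1.5 to 6.67 ± 0.58 CPM (SD, n = 3 each), a change of -2.12 on the log2 scale with a standard error of 0.097 (limma, adjusted p = 0.0036). ENST00000680653.1 fell from 32.0 ± 1.7 to 6.67 ± 0.58 CPM (SD, n = 3 each). Within each pair the values of the transcripts differed by at most 1 CPM in any library, and whether they share reads was not given. Without UT-143 replicate 3 the changes of ENST00000612821.4 and ENST00000681704.1 were 3.21 and -2.06 on the log2 scale, and both remained past the threshold (limma, adjusted p = 0.0078 and 0.0023). None of these 4 transcripts passed it when any 1 of the other 5 libraries was left out. Their changes in those fits stayed at 2.62 to 3.13 for the rises and -2.06 to -2.15 for the falls on the log2 scale.

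**Figure D3:**
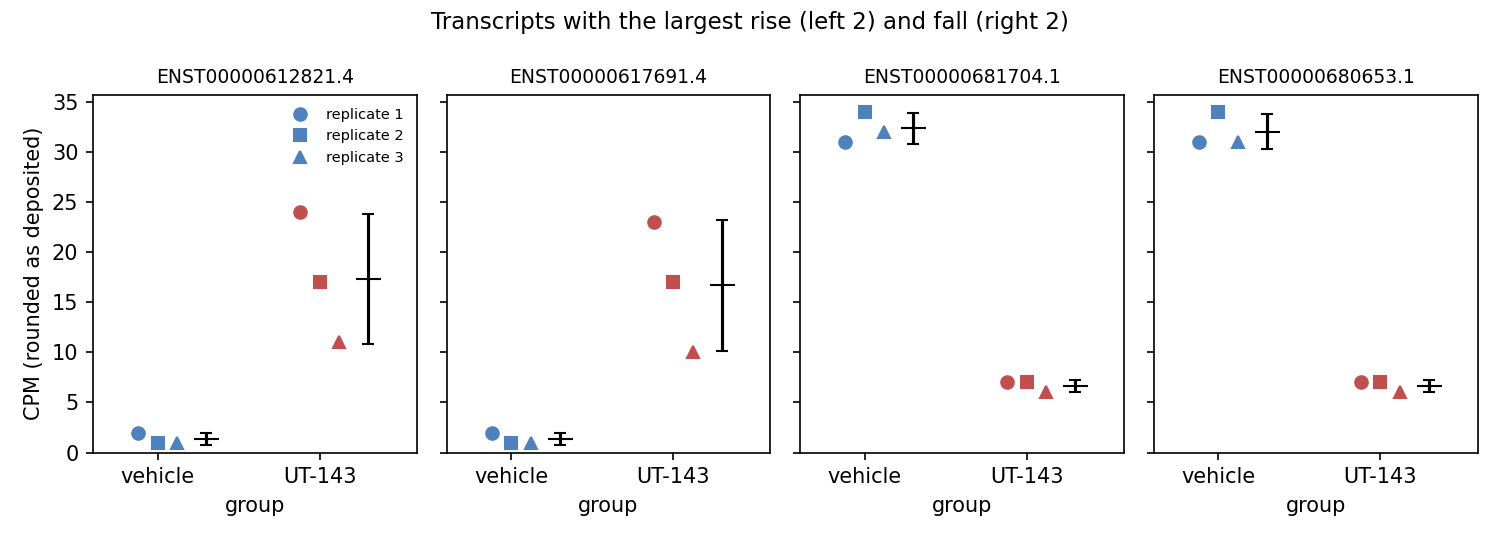
CPM (rounded as deposited) of the 2 transcripts with the largest rise and the 2 with the largest fall, by group, with 1 symbol per replicate and the mean ± SD of 3 libraries in black. The UT-143 values lie between 10 and 24 for the transcripts that rose, against 1 to 2 in vehicle, and at 6 or 7 for those that fell, against 31 to 34 in vehicle.

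In the authors' deposited table, 6025 transcripts had an unadjusted p under 0.05, of which 2105 had a ratio of UT-143 to vehicle above 1 and 3920 a ratio below 1. After Benjamini-Hochberg adjustment of the p-values in the authors' deposited table, 0 transcripts were under 0.05. The limma fit, which differs from that test in scale, variance assumption and moderation, called 1188. With 3 libraries per group a 2-sided exact permutation test of a single transcript cannot go below p = 0.1.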

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

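The alternatives to the fit without UT-143 replicate 3, 1 transcript per distinct set of values, the mean of 20 CPM and array weights were chosen after seeing the data. With 6 libraries, other pseudocounts, moderation settings and 1 transcript per distinct set of values kept the number of changed transcripts within 1.5 times of 1188, and the first 2 filters removed no transcript. Trimmed mean and median-of-ratios scaling raised the higher transcripts to 734 and 696, and quantile normalization gave 1409 higher and 1966 lower (3375 in all). Trimmed mean and median-of-ratios scaling gave UT-143 replicate 3 factors of 0.923 and 0.915, against 0.996 to 1.033 in the other libraries. They moved the median change over all transcripts from -0.058 to 0.0058 and 0.0055 on the log2 scale. The cause of the changed counts was not tested. A fit of only the 10908 transcripts with a mean of at least 20 CPM called 366 higher and 483 lower, where the fit of all transcripts called 214 and 285 of these. The cause was not tested. An adjusted p under 0.01 left 9 (2 higher, 7 lower), and a change of at least 1 on the log2 scale left 248 (102 higher, 146 lower). Leaving out 1 library gave 0 to 8206 changed transcripts (0 to 3048 higher, 0 to 5158 lower). The highest values came without UT-143 replicate 3, and 0 without any 1 of the others. Array weights from limma gave 21265 changed transcripts (8918 higher, 12347 lower), but the estimation of the weights stopped before it converged, with a weight of 29.8 for UT-143 replicate 2 and 0.035 for UT-143 replicate 3. With the replicate block, 0 transcripts passed in limma and 7941 had an unadjusted p under 0.05. The labels share only a number. Not every library correlated best with its own, but UT-143 replicate 3 dominates that check, so pairing is not excluded.

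Without UT-143 replicate 3, trimmed mean scaling, median-of-ratios scaling and robust moderation gave 5558, 5297 and 4843 higher transcripts against 3048. The totals of changed transcripts were 11481, 11196 and 11768 against 8206. With 1 transcript per distinct set of values, 6087 of 19559 were changed (2444 higher, 3643 lower), against 8206 of 35246. An adjusted p under 0.01 left 2037 (645 higher, 1392 lower), and a change of at least 1 left 246 (97 higher, 149 lower). A fit of only the 11037 transcripts with a mean of at least 20 CPM called 3768 (1539 higher, 2229 lower), where the fit of all transcripts called 2970 of these. The cause was not tested. Leaving out 1 more library gave 2904 to 6405 changed transcripts (1087 to 2433 higher, 1679 to 3972 lower), with the lowest total without UT-143 replicate 1. There, 1 UT-143 library is left and is assumed to vary like the vehicle libraries. The values were 3099 without UT-143 replicate 2 and 4195 without vehicle replicate 2.

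The 4 named transcripts changed by 1.76 to 3.46 in size in 72 comparisons with other settings. All kept their direction, fixed by the naming rule except under the scalings. Adjusted p in limma ran from 9.2e-04 (1.4e-06 with the unconverged array weights) to 0.21. The threshold was missed in 24, under the replicate block and without any 1 library but UT-143 replicate 3. Count models were not run, as rounded values give no reads back, nor gene list tests, as no transcript could be named. Rounding limits transcripts of a few CPM.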

Other observations

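All tests below were chosen after the results they concern had been seen, and 2 were changed after a first run, as stated with each. Among the 10 ways of splitting the 6 libraries into 3 and 3, the real split called 1188 transcripts and was the only 1 with that many, and the highest count of the others was 0. With 10 splits the share cannot fall under 0.05. At an unadjusted p under 0.05 the real split gave 9297 transcripts and the highest of the others 682. Every other split mixes vehicle and UT-143 libraries in both groups. A difference between vehicle and UT-143 then adds to the spread within groups, which lowers these counts. The other splits therefore do not give the count expected without an effect.

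Much of the change in UT-143 replicates 1 and 2 was also present in UT-143 replicate 3. Across transcripts, the change from the vehicle mean in replicates 1 and 2 correlated at 0.59 with that in replicate 3, against 0.069 in 100 simulations of unchanged groups with independent errors that share the vehicle libraries. The covariance was 0.136, against 0.0051 simulated. Of the 8206 transcripts called without replicate 3, its value lay on the same side of the vehicle mean in 6879 (83.8%), in 72.4% of the higher and 90.6% of the lower ones. In the simulations the same side was shared by 54.7% of as many transcripts with the largest changes in replicates 1 and 2. The difference between the higher and the lower ones was not tested, and replicate 3 lay below the vehicle mean in 56.9% of all transcripts. Of the 246 that also changed by at least 1 on the log2 scale, 244 had the same direction in replicate 3.

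UT-143 replicate 3 nevertheless stands apart, with a standard deviation of 0.62 in its log2 difference from the mean of replicates 1 and 2, against 0.13 between those 2. Counting noise from a shallower library would shrink with abundance to 0.31 of its size, but the spread at 50 CPM or more was 0.78 of that under 10 CPM (95% bootstrap interval 0.755 to 0.803 over distinct sets of values), which argues against it as the whole cause. The interval treats distinct sets as independent, though some are near copies of each other, so it is likely too narrow. It measures no variation between libraries. The ratio of 0.78 was first taken over all transcripts, where it was 0.86. A stronger form of the same change as the whole cause is argued against, if the calls are true, by 937 of the 8206 transcripts (11.4%). In these, replicate 3 lay beyond all 3 vehicle values on the opposite side. These were 20.4% of the higher and 6.11% of the lower transcripts, and 15.9% and 11.6% of them after median-of-ratios scaling. In 100 simulations where replicate 3 was the change in replicates 1 and 2 times 1.45, with the spread between those replicates, the share was 0.0146%. These simulations took each observed change as true, whereas a false call can fall on either side, and the number of false calls is unknown. The factor of 1.45 is the observed slope of the change in replicate 3 on that in replicates 1 and 2. A stronger form therefore remains open as a part of the difference. Of the 246 transcripts changed by at least 1 on the log2 scale, 1 lay beyond all vehicle values on the opposite side. Among these larger changes the test does not argue against a stronger form. The median difference of replicate 3 from replicates 1 and 2 ran from -0.22 under 10 CPM to 0.16 at 50 CPM or more. The levels were set by the mean of all 6 libraries, which includes replicate 3, so part of this trend is built in. A shift in the value distribution between libraries is argued against as the whole cause too, because quantile normalization left a standard deviation of 0.51, against 0.15 between replicates 1 and 2 after the same step. The bound for this test was at first 0.8 of the deposited value, 0.497, and was then changed to 2 times the value between replicates 1 and 2, and the standard deviation lay above both. A difference in exposure time, culture, RNA quality or library preparation, and a library of another origin, may contribute and were not tested.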
